A study of Mus musculus with 16 samples.

How the data were processed

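Protein signals of 16 liver samples of male C3H/HeJ mice were analysed, 7 Ctnnb1-mutated tumors and 3 control livers of the phenobarbital (PB) arm, and 3 Ha-ras-mutated tumors and 3 control livers of the arm without PB. Groups and replicate numbers were taken from the sample titles. Genotype and PB treatment go together, since each tumor genotype comes from 1 arm. The labels disagree on the treatment. The series' design text gives diethylnitrosamine (10 or 90 µg per g, to mice aged 2 or 6 weeks) followed by a diet with 0.05% PB or none for 28 to 36 weeks, the sample characteristics give 27 weeks, and the sample protocols describe 28 days of PB in drinking water. The doses and ages at injection were not assigned to samples here, so they may also differ between the arms. Per the labels' protocols, frozen tissue was ground and lysed in an 8-fold excess of a denaturing Zeptosens buffer, and signals came from fluorescent anti-species secondary antibodies on a reverse-phase protein array.

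Each deposited sample file holds an intensity (relative fluorescence) for 183 rows, which are 158 antibodies, 19 blanks with secondary antibody only and 6 Alexa647 reference rows. Whether the authors scaled these intensities before deposit is not given in the sources used here. The authors' series value table holds log2 values for the same antibodies. Set against the deposited intensities, 146 of 158 antibodies in it equal the log2 of the intensity (for 145 of them less 1 blank) times 1 factor per sample, less the median of the 3 control livers of the arm (within 0.01 log2 in at least 12 samples, and in all 16 samples for 137). The factor followed the inverse mean of the Alexa647 rows within 0.0908 log2. Because each arm is centred on its own controls, that table cannot give PB against no-PB control liver or the direct comparison of the tumors, and it was used as an alternative for the other comparisons only. The other 12 antibodies had no match, and 1 matched without a blank. An antibody was called dim in a sample when its intensity was under 2 times its blank. This limit and the matching of blanks were chosen after the data had been seen. By median signal, 26 antibodies were dim.

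The intensities were log2 transformed and each sample was centred on its median over the antibodies positive in all samples. The 3 non-positive values (CYP2B6_3 in Ha-ras tumor 3, GLUL in Ctnnb1 tumor 6 and ACTB in PB control liver 6) were treated as missing. Blanks were not subtracted, so differences of dim antibodies are understated. One limma fit of 4 group means (R 4.3.3, limma 3.58.1, 12 residual and 2.66 prior degrees of freedom) gave all 5 comparisons, with Benjamini-Hochberg adjustment over the 158 antibodies within each and a threshold of 0.05. Log2 differences are given with limma's standard error. For an antibody dim in every sample of a group, the fold is a lower bound, the mean of the brighter group over the mean of the dim group with each dim sample at the higher of its signal and its limit. Phosphorylation was also tested relative to total protein in 45 pairs, on the difference of log2 signals.

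A total of 15 protein lists had been fixed by subject before the data were examined, and 13 with at least 3 antibodies were tested with camera (preset correlation 0.01, 155 antibodies with complete values, adjustment over the lists) and with an estimated correlation. The lists were MAPK/ERK cascade, PI3K/Akt/mTOR and translation, Wnt/beta-catenin and its targets, tyrosine kinases, stress MAP kinases, STAT and NF-kB, apoptosis and p53, cell cycle, lipid and energy metabolism, carbohydrate metabolism, xenobiotic metabolism and oxidative stress, chaperones and cell stress, other cell types, reference proteins and phosphorylation-site antibodies. Antibodies to name were also fixed by rule, per comparison the 25 calls with the largest difference, up to 4 members with the smallest p of each list with a call, the pairs past the threshold up to 10, and in every case antibodies to beta-catenin, Ras, glutamine synthetase, ERK, MEK and Akt. Some antibodies that the rule names are left out of the text. GAPDH, CYP1A2_1, CYP1A2_2, CYP2B6_2, CYP2D6, CYP2E1_1, CYP2E1_2, CYP3A4_1, CYP3A4_2 and UGT1A1 are named beyond the rule in places, chosen after their values were seen. Of 101 protein symbols, 91 match a mouse gene name in the RefSeq table of assembly GRCm38.p6 without regard to case. The array gives no genomic coordinates.

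The fit was tested on simulated data with the real antibodies' means and spreads, 40 of 158 antibodies changed and 20 runs per setting. The noise was drawn independently for each antibody, with 1 spread for all groups. In the real data the median SD was 0.213 in Ctnnb1 tumors and 0.108 in PB control liver, and antibodies may be correlated. The shares below therefore need not hold for the real samples. For Ha-ras tumors against control liver it recovered 87.7% of changes of 1 log2 and 45% of changes of 0.5 log2, and for Ctnnb1 tumors against PB control liver 88.8% and 51.1%. Without centring, 4.77% and 3.58% of the calls were false in these comparisons. With centring they were 8.36% and 18.1%, and with nearly equal numbers of changes up and down 5.82% and 9.42%. The excess was smaller with nearly equal numbers but did not vanish. Each setting had its own random draws, so what accounts for the excess was not decided.

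Alternatives planned before the data were examined were no centring, quantile normalization, the authors' value table, leaving out the antibodies with the lowest signal, a trend and robust prior, a fit of the compared groups alone, array weights (for the difference of the tumor effects), non-positive values set to the lowest positive signal of the sample, each replicate left out, and the replicate number as a block. Scaling to the Alexa647 rows, blank subtraction, a filter at 2 times the blank, array weights for the other comparisons and cameraPR on all 158 antibodies were added after the data had been seen. A further run that left out 2 Ctnnb1 tumors picked for their low glutamine synthetase was made and set aside, because it chose samples by a measured outcome. Figures and group tests used Python with numpy, pandas and matplotlib.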

Results

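Protein levels and phosphorylation were measured in 16 mouse liver samples with a reverse-phase protein array, an assay in which tissue lysates are spotted on a chip and each antibody is read as a fluorescence signal over all spotted samples. The samples fell into 4 groups: 7 tumors with a mutated Ctnnb1 (the gene of beta-catenin, the transcriptional effector of Wnt signalling) and 3 control livers, both from mice given phenobarbital (PB, a barbiturate that induces drug-metabolising enzymes in liver), and 3 tumors with a mutated Ha-ras (a GTPase upstream of the MEK and ERK kinases) and 3 control livers from mice without PB. All mice were males of the C3H/HeJ strain that had, per the series' design text, received a single injection of diethylnitrosamine, a liver carcinogen. The labels do not say that the samples came from separate animals, so the p-values measure the spread between these samples, which may be partly technical. Each sample had values for 158 antibodies, 50 of them against a phosphorylation site. The median signal per sample lay between 0.466 and 0.791 relative fluorescence units, and that of the secondary-antibody blanks between 0.081 and 0.138. Of the 158 antibodies, 91 read at 2 times their blank or more in every sample and 7 read below that limit in every sample. The number of samples per group limits the precision. Antibodies are named as the files name them, with human-style symbols and a final number where several antibodies target a protein. Which mouse homolog an antibody to CYP2B6, CYP2C8 or CYP3A4 bound is not known, since no mouse gene has those names.

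The first comparison asked which proteins and sites differed between Ha-ras-mutated tumors and control liver without PB. Phosphorylated ERK1 (MAPK3_P-T202/Y204), the terminal kinase of the MAP kinase cascade downstream of Ras, was 4.02-fold higher in the tumors (log2 difference 2.01 ± 0.24 SE, n = 3 and 3, limma adjusted p = 8.2e-05), with a signal of 6.41 ± 2.83 (SD) against 1.43 ± 0.09. Phosphorylated MEK1 (MAP2K1_P-S217/S221), which activates ERK, rose 1.71-fold, and the ERK-activated ribosomal S6 kinases rose 1.95-fold (RPS6KA1_P-T573) and 1.74-fold (RPS6KA3_P-T353/T356). Several antibodies to enzymes of drug metabolism fell in the same tumors. The CYP2E1 antibodies, against an ethanol-inducible cytochrome P450, were 3.80-fold and 6.14-fold lower, CYP2C8 was 2.68-fold lower, and POR, the reductase that supplies electrons to cytochromes P450, was 2.07-fold lower.

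In all, 22 of 158 antibodies differed between Ha-ras tumors and their control liver at an adjusted p under 0.05, 16 higher and 6 lower. Scaling to the Alexa647 reference rows instead of the median gave 20 higher and 4 lower. Of the 18 antibodies of the MAPK/ERK cascade list, 4 rose, the transcription factor ELK1 fell (1.99-fold lower), and 13 did not pass. With adjustment over the list alone, 6 were higher and 1 lower, and the list as a whole did not pass camera, limma's set test (adjusted p = 0.143). Total ERK1 (MAPK3) had a log2 difference of 0.52 ± 0.18 (adjusted p = 0.085) and passed in 7 of 19 alternatives, the Alexa647 scaling among them (0.71, adjusted p = 0.00937). MEK1 (MAP2K1) had a log2 difference of -0.29 ± 0.23 and MEK2 (MAP2K2) of -0.09 ± 0.14. Relative to its total protein, phosphorylated ERK1 was 2.80-fold higher (adjusted p = 4.9e-04), RPS6KA1_P-T573 2.08-fold higher and MAP2K1_P-S217/S221 2.08-fold higher, while STAT3_P-Y705 was 1.66-fold lower, with a log2 difference of -0.11 ± 0.10 for the site itself. These were the 4 of 45 phospho to total pairs that passed. The MAP2K1 pair was lost without controls 1 or 2 or tumors 1 or 2 (adjusted p up to 0.0985) and in the authors' value table (adjusted p = 0.0506), and the STAT3 pair without control 2 or tumor 1 (up to 0.0985), either of which left 2 pairs.

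Of the 19 antibodies of the PI3K/Akt/mTOR and translation list, 6 rose in Ha-ras tumors (7 adjusted over the list alone) and the list did not pass (adjusted p = 0.143). MTOR_P-S2448, on the growth kinase mTOR, was 1.79-fold higher, GSK3B_P-S9, the inhibitory site of glycogen synthase kinase 3 beta, 2.40-fold higher and the translation factor EIF2A 1.52-fold higher. PDK1_P-S241 was 1.30-fold and GSK3B 1.31-fold higher. AKT1 (log2 0.07 ± 0.15) and AKT1_P-S473 (-0.18 ± 0.18) did not pass. Among 7 stress MAP kinase antibodies, 2 rose, the kinase site MAPK8_P-T183/Y185 (1.85-fold) and the transcription factor JUN, which read below 2 times its blank in all 3 controls and was at least 1.12-fold higher. Of 13 STAT and NF-kB antibodies, STAT3 (1.54-fold) and STAT3_P-S727 (1.60-fold) rose. STAT3_P-S727 read below 2 times its blank in 2 of the 3 controls and 1 of the 3 tumors. BAX, a pro-apoptotic protein, was 2.01-fold higher, and 5 of the 6 antibodies of its list did not pass. PAK1_P-S141 rose by 0.59 ± 0.17 on the log2 scale. As a set, the 50 phosphorylation-site antibodies lay higher than the rest (11 rose, none fell, adjusted p = 0.00175), but adjusted p = 0.345 with an estimated correlation.

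Of the 17 antibodies of the xenobiotic metabolism and oxidative stress list, 5 fell in Ha-ras tumors, none rose, and 12 did not pass. Adjustment over the list alone gave the same 5. Camera placed the list lower than the other antibodies (adjusted p = 1.4e-04), but adjusted p = 0.317 with an estimated correlation. CYP2B6_3 had the largest difference (log2 -4.99 ± 0.89, adjusted p = 0.0024). It read 31.3, 24.5 and 11.5 in the controls, and 3.81, 0.126 and -8.84 in the tumors. The last value has no logarithm, and 2 of the 3 tumors read below 2 times the blank, so the size is uncertain. Without tumor 2, which leaves 1 tumor with a logarithm that is taken to vary like the other groups, the log2 difference was -2.56. CYP2B6_3 did not pass in a fit of these 2 groups alone (adjusted p = 0.0796, with a range over all alternatives of 6.2e-09 to 0.0796). The other antibodies to this protein gave log2 differences of -0.07 ± 0.29 (CYP2B6_1) and 0.02 ± 0.16 (CYP2B6_2). Of 15 antibodies of the Wnt/beta-catenin list, GSK3B and GSK3B_P-S9 rose and both CYP2E1 antibodies fell. Glutamine synthetase (GLUL), a product of beta-catenin activity in hepatocytes around the central vein, had a log2 difference of -3.57 ± 1.45 (adjusted p = 0.143), with 2 of 3 tumors below 2 times the blank. It was -5.68 without tumor 1, which passed (adjusted p = 0.00441), and -2.29 without tumor 3. The log2 difference of CTNNB1 was 0.78 ± 0.43 (adjusted p = 0.321), that of CTNNB1_P-S675 0.38 ± 0.21, of CTNNB1_P-T41/S45 0.36 ± 0.18 and of HRAS -0.16 ± 0.13.

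The 22 Ha-ras calls rested on 3 samples per group. Of them, 14 passed with any 1 of the 6 samples left out. JUN and GSK3B were each lost without any 1 of the 3 controls, tumor 2 or tumor 3 (adjusted p up to 0.153 and 0.129). PAK1_P-S141 was lost without controls 2 or 3 or tumors 1 or 2 (up to 0.121), and STAT3 without controls 2 or 3 or tumors 1 or 3 (up to 0.11). STAT3_P-S727 was lost without controls 2 or 3 or tumor 1 (up to 0.0745), EIF2A without control 2 or tumor 1 (up to 0.0745), and PDK1_P-S241 (up to 0.0693) without controls 1 or 3 or tumor 3. Without tumor 3, 4 lists passed in place of 2, the MAPK/ERK list (higher, adjusted p = 0.0376) and the tyrosine kinase list (lower, adjusted p = 0.0417) being added. MAP2K1_P-S217/S221 was lost in a fit of the 2 groups alone (0.0796). POR and ELK1 were lost with the Alexa647 scaling (0.0517 and 0.0733) and in the authors' value table (0.0601 and 0.0796), and JUN, GSK3B, PAK1_P-S141, PDK1_P-S241, STAT3 and STAT3_P-S727 under further alternatives too.

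**Figure D1:**
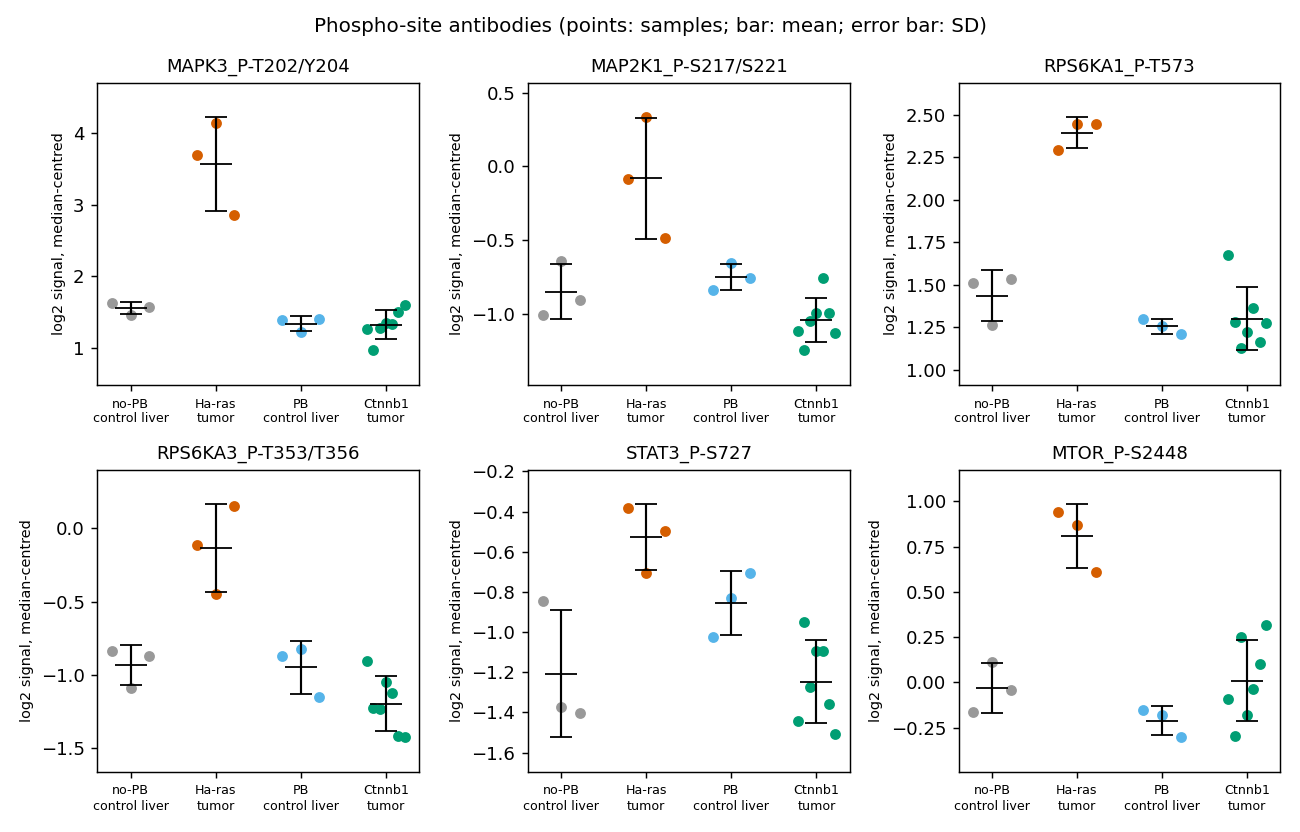
Median-centred log2 signal of 6 phospho-site antibodies in each sample of the 4 groups, with a horizontal bar at the mean and error bars of 1 SD. MAPK3_P-T202/Y204 averaged 3.56 in the 3 Ha-ras tumors, against 1.56 and 1.34 in the control livers without and with PB and 1.33 in the 7 Ctnnb1 tumors.

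The same question was asked of the Ctnnb1-mutated tumors against control liver of mice on PB. No antibody passed in this comparison. The limma fit called 0 of 158 antibodies (25 at an unadjusted p under 0.05), and the smallest adjusted p was 0.2503. GLUL read from -0.0233 to 54.1 in the 7 tumors and from 2.27 to 27.9 in the 3 control livers. Its log2 difference was 1.53 ± 1.26 SE (adjusted p = 0.470), without the tumor whose negative signal has no logarithm. With that tumor at the lowest positive signal the difference was 0.31, and without PB control liver 6 it was 0.37. CTNNB1 had a log2 difference of -0.09 ± 0.36, CTNNB1_P-S675 of -0.15 ± 0.18 and CTNNB1_P-T41/S45 of 0.01 ± 0.16. No antibody of the ERK cascade passed, with log2 differences of -0.01 ± 0.20 for MAPK3_P-T202/Y204, 0.26 ± 0.16 for MAPK3, -0.29 ± 0.15 for MAP2K1_P-S217/S221, -0.25 ± 0.19 for MAP2K1 and -0.29 ± 0.12 for MAP2K2, which was lower in 7 of 7 tumors than in any control liver. HRAS (-0.24 ± 0.11), AKT1 (-0.03 ± 0.13) and AKT1_P-S473 (-0.36 ± 0.16) did not pass either. The antibodies to drug-metabolising enzymes gave log2 differences of 0.16 ± 0.68 for CYP2B6_3, -0.32 ± 0.21 for CYP2C8, -0.38 ± 0.21 for POR, -0.36 ± 0.11 for CYP2D6 (adjusted p = 0.2503, lower in 7 of 7 tumors than in any control liver), -0.43 ± 0.36 for CYP2E1_1, -0.48 ± 0.43 for CYP2E1_2 and 0.10 ± 0.63 for CYP1A2_1. Without Ctnnb1 tumor 6 those of CYP1A2_1, CYP2E1_1 and CYP2E1_2 were 0.62 ± 0.19 (adjusted p = 0.261), -0.20 and -0.23.

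None of the 13 lists tested passed camera in the Ctnnb1 tumors (smallest adjusted p = 0.134). Adjusted over the list alone, 1 of 13 STAT and NF-kB antibodies was lower, JAK1. The authors' values gave 3 that passed, the stress kinase and chaperone lists higher and the xenobiotic list lower, and the stress kinase list also passed with the replicate number as a block. The 17 xenobiotic antibodies had a median log2 difference of -0.25 and the 18 MAPK/ERK antibodies of -0.24, where the median over all 158 antibodies was -0.14. One of 45 phospho to total pairs passed. JAK1_P-Y1022/Y1023, the activation site of the cytokine receptor kinase JAK1, was 1.47-fold higher relative to JAK1 (log2 0.56 ± 0.13, adjusted p = 0.0246). The site alone had a log2 difference of 0.17 ± 0.11 and JAK1 of -0.39 ± 0.11, so the lower total made the larger part of the ratio. This call was lost without tumor 3 or any 1 of the 3 control livers (adjusted p up to 0.25), and in the authors' value table (adjusted p = 0.0651).

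The control livers with and without PB were compared for what the treatment did in liver outside tumors. PB control liver had more of 3 proteins of drug metabolism. CYP2C8 was 5.62-fold higher (log2 2.49 ± 0.25 SE, n = 3 and 3, limma adjusted p = 1.2e-05), with a signal of 8.29 ± 2.05 (SD) against 1.28 ± 0.33. CYP2B6_1, against a P450 that PB is known to induce, was 3.06-fold higher (adjusted p = 0.00468), and POR was 2.38-fold higher (adjusted p = 0.00965). CYP2B6_3 did not pass in spite of a large difference (log2 3.04 ± 0.80, adjusted p = 0.080), and CYP2B6_2 gave 0.06 ± 0.16.

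These 3 were the only calls among 158 antibodies in the control livers (14 at an unadjusted p under 0.05). Under quantile normalization the 3 calls were 2 higher and 1 lower (MAP2K1, log2 -1.91), and POR was not among them (log2 0.37, adjusted p = 0.31, with a range over all alternatives of 8.3e-04 to 0.31). POR was also lost without PB control livers 5 or 6 or no-PB control liver 3 (adjusted p up to 0.0652). Of the 17 xenobiotic antibodies, 3 rose and 7 were higher when adjusted over the list alone. The list lay higher than the other antibodies (adjusted p = 1.7e-08) and passed with an estimated correlation (adjusted p = 0.0431). Examples that did not pass were CYP1A2_1 (log2 1.99 ± 0.75), CYP3A4_2 (1.96 ± 0.66) and UGT1A1, a glucuronidating enzyme (0.93 ± 0.32). No other list passed. No phospho to total pair of 45 passed in limma (3 at an unadjusted p under 0.05), and 1 passed without no-PB control liver 1. GLUL (2.15 ± 1.45), CTNNB1 (-0.07 ± 0.43), CTNNB1_P-S675 (0.27 ± 0.21), CTNNB1_P-T41/S45 (0.22 ± 0.18), HRAS (-0.07 ± 0.13), MAPK3 (0.12 ± 0.18), MAPK3_P-T202/Y204 (-0.21 ± 0.24), MAP2K1 (-0.26 ± 0.23), MAP2K1_P-S217/S221 (0.10 ± 0.17), MAP2K2 (0.06 ± 0.14), AKT1 (0.10 ± 0.15) and AKT1_P-S473 (-0.07 ± 0.18) did not pass. Only 3 samples stood on each side, and the mice of the 2 arms may have differed in more than PB.

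**Figure D2:**
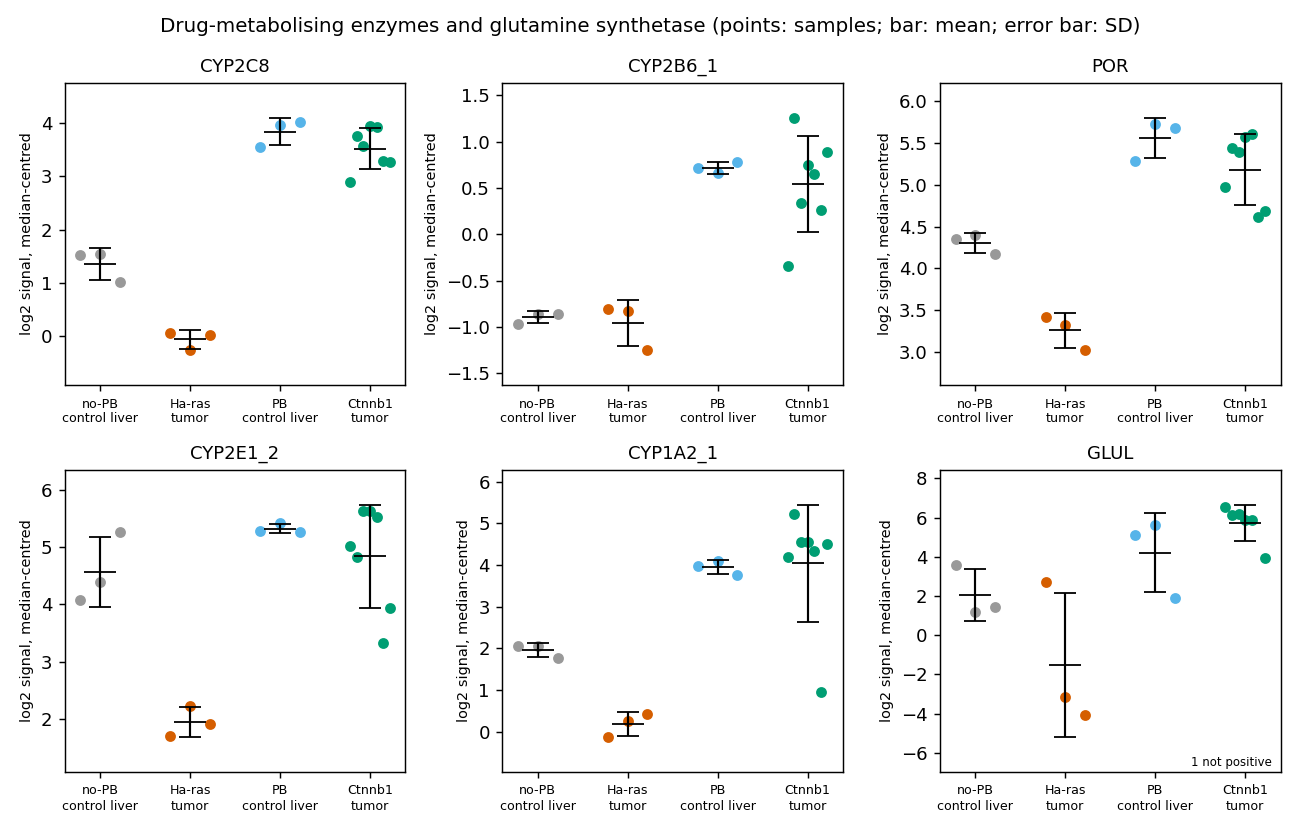
Median-centred log2 signal of 5 antibodies to drug-metabolising enzymes and of GLUL in each sample, with a horizontal bar at the mean and error bars of 1 SD over the positive values. CYP2C8 averaged -0.07 in the 3 Ha-ras tumors, 1.36 in control liver without PB, 3.85 in control liver with PB and 3.53 in the 7 Ctnnb1 tumors.

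The tumor types were also set directly against each other. This comparison carries the PB treatment with it, since all Ctnnb1 tumors and no Ha-ras tumors had PB. It also carries any difference between the arms in carcinogen dose or age at injection. Ctnnb1 tumors were higher in 8 of 17 antibodies of the xenobiotic list and in GLUL. CYP2C8 was 12.1-fold higher (log2 3.59 ± 0.21 SE, n = 7 and 3, limma adjusted p = 8.7e-09), CYP1A2_1 14.5-fold, CYP2E1_1 5.24-fold, CYP2E1_2 7.41-fold, CYP3A4_2 4.70-fold (2 of 3 Ha-ras tumors below 2 times the blank), POR 3.80-fold and CYP2B6_1 2.84-fold. Other antibodies to the same proteins did not pass, with log2 differences of 0.07 ± 0.15 for CYP1A2_2, 0.04 ± 0.13 for CYP2B6_2 and 0.44 ± 0.18 for CYP3A4_1. CYP2B6_3 read 239 ± 42.8 (SD) in the 7 Ctnnb1 tumors (log2 difference 8.19 ± 0.78, 2 of 3 Ha-ras tumors below 2 times the blank). Without Ha-ras tumor 2 the difference was 5.76, so its size is uncertain. GLUL was higher by 7.25 ± 1.26 on the log2 scale in the 6 Ctnnb1 tumors with a positive signal (adjusted p = 6.1e-04), with 2 of the 3 Ha-ras tumors below 2 times the blank. Its size is uncertain too, since the alternatives gave from 5.47 (array weights) to 9.37 (without Ha-ras tumor 1), and with the replicate number as a block it was not called (adjusted p = 0.0698). Phosphorylated ERK1 was 4.71-fold lower in Ctnnb1 tumors (log2 -2.24 ± 0.20, adjusted p = 1.2e-06, lower in 7 of 7 than in any Ha-ras tumor). RPS6KA1_P-T573 was 2.14-fold lower, RPS6KA3_P-T353/T356 2.08-fold, MAP2K1_P-S217/S221 1.95-fold and RPS6KA1_P-S380 1.86-fold lower.

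In this comparison 30 antibodies passed, 9 higher and 21 lower in Ctnnb1 tumors. The split moved with the scaling. Without centring it was 19 higher and 9 lower, and with scaling to the Alexa647 rows 10 higher and 10 lower. The median log2 difference over all 158 antibodies was -0.11 with centring and 0.16 without. The direction of small differences therefore holds relative to the median antibody only. Of 17 xenobiotic antibodies, 8 rose, none fell and 9 did not pass (9 higher adjusted over the list alone). The list passed with the preset (adjusted p = 5.9e-13) and with an estimated correlation (adjusted p = 0.00663). Of 18 MAPK/ERK antibodies, 6 fell, none rose and 12 did not pass (adjusted p = 0.00639, but adjusted p = 0.0993 with an estimated correlation). Among the 50 phosphorylation-site antibodies 13 fell and none rose (adjusted p = 1.3e-04, but adjusted p = 0.266 with an estimated correlation).

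Of the 19 PI3K/Akt/mTOR and translation antibodies, 5 were lower in Ctnnb1 than in Ha-ras tumors, among them MTOR_P-S2448 (1.74-fold), GSK3B_P-S9 (1.97-fold), PDK1_P-S241 (1.35-fold) and EIF2A (1.42-fold). Of 13 STAT and NF-kB antibodies, 3 were lower, STAT3 (1.84-fold), STAT3_P-S727 (1.64-fold) and JAK1 (1.26-fold). STAT3_P-S727 read below 2 times its blank in 3 of 7 Ctnnb1 and 1 of 3 Ha-ras tumors. The stress kinase antibodies MAPK8_P-T183/Y185 (1.73-fold) and MAP2K4 (1.22-fold) were lower too, as 2 of 7 in their list. In the lipid and energy metabolism list 3 of 6 were lower, the activation site of the energy sensor AMPK (PRKAA1_P-T172, 2.27-fold), the hepatocyte transcription factor HNF4A (1.40-fold) and PPARA_2 (1.26-fold), an antibody to a regulator of fatty acid oxidation. HDAC6 (1.63-fold, below 2 times its blank in 5 of 7 Ctnnb1 tumors) was also lower. None of the Wnt/beta-catenin, PI3K, STAT, stress kinase or lipid lists passed camera (adjusted p of 0.472, 0.472, 0.669, 0.472 and 0.621). In the Wnt/beta-catenin list 4 of 15 were higher (GLUL, CYP1A2_1 and both CYP2E1 antibodies) and GSK3B_P-S9 was lower. Adjusted over the list alone, 4 were higher and 4 lower in the Wnt/beta-catenin list, 6 lower in the PI3K list, 4 lower in the stress kinase list and 2 lower in the apoptosis list. CTNNB1 passed without Ctnnb1 tumor 7 (-1.11, adjusted p = 0.0248). CTNNB1 with all samples (log2 -0.94 ± 0.36, adjusted p = 0.080), CTNNB1_P-S675 (-0.25 ± 0.18), CTNNB1_P-T41/S45 (-0.13 ± 0.16), HRAS (-0.15 ± 0.11), MAPK3 (-0.15 ± 0.16), MAP2K1 (-0.23 ± 0.19), MAP2K2 (-0.13 ± 0.12), AKT1 (-0.01 ± 0.13) and AKT1_P-S473 (-0.24 ± 0.16) did not pass.

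Of 45 phospho to total pairs, 10 differed between the tumor types. Relative to the total protein, Ctnnb1 tumors were lower in 8 pairs, among them MAPK3_P-T202/Y204 (4.25-fold, adjusted p = 7.7e-07), PRKAA1_P-T172 (2.41-fold), RPS6KA1_P-T573 (1.85-fold), MAP2K1_P-S217/S221 (1.67-fold), MAPK8_P-T183/Y185 (1.63-fold), MTOR_P-S2448 (1.45-fold) and PDK1_P-S241 (1.36-fold). They were higher in STAT3_P-Y705 (1.80-fold) and JAK1_P-Y1022/Y1023 (1.37-fold). These 2 ratios came mainly from lower totals, since the sites themselves had log2 differences of -0.03 ± 0.08 and 0.12 ± 0.11, and STAT3 and JAK1 of -0.88 and -0.33. Without Ha-ras tumor 2 the number of pairs was 3, those of MAPK3, RPS6KA1 and STAT3, which passed with any 1 sample left out. The MAPK8 pair was also lost without Ha-ras tumor 1, the JAK1 pair without Ha-ras tumor 3, and the MAP2K1 pair without Ctnnb1 tumors 1, 2, 4, 6 or 7 or Ha-ras tumor 1 (adjusted p up to 0.401). The PDK1 total read below 2 times its blank in 13 of 16 samples. Of 28 calls between the tumor types tested in this way, 21 passed with any 1 sample left out. HDAC6 was lost without Ctnnb1 tumors 1 to 4 or Ha-ras tumors 2 or 3 (adjusted p up to 0.173), JAK1 without Ctnnb1 tumors 2, 3, 4, 6 or 7 or Ha-ras tumors 2 or 3 (up to 0.334) and MAP2K4 without Ctnnb1 tumors 2, 3 or 6 or any 1 Ha-ras tumor (up to 0.214). EIF2A was lost without Ha-ras tumor 1 (0.0767), and GSK3B_P-S9 (0.0567) and PPARA_2 (0.214) without Ha-ras tumor 3, where PPARA_2 and JAK1 had log2 differences of -0.19 and -0.18. Scaling to the Alexa647 rows ended the calls of HNF4A, PDK1_P-S241, STAT3_P-S727, EIF2A, PPARA_2, JAK1, MAP2K4 and HDAC6, among others, and leaving out the centring ended that of RPS6KA1_P-S380 (adjusted p = 0.0681).

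Whether the tumor effect itself differed between the arms was tested as the difference of the 2 tumor to control differences, which sets aside a PB effect that is equal in tumor and control liver. The effect on phosphorylated ERK1 was lower in Ctnnb1 than in Ha-ras tumors by 2.02 ± 0.31 on the log2 scale (limma adjusted p = 0.00179). The upstream and downstream kinase sites differed the same way, MAP2K1_P-S217/S221 with -1.06 ± 0.23, RPS6KA3_P-T353/T356 with -1.04 ± 0.22 and RPS6KA1_P-T573 with -0.92 ± 0.17. STAT3_P-S727 (-1.07 ± 0.23), STAT3 (-0.91 ± 0.23) and PDK1_P-S241 (-0.48 ± 0.13) were lower too. STAT3_P-S727 read below 2 times its blank in 9 of 16 samples, among them all 3 PB control livers, so the size of its difference is uncertain. CYP2B6_3 was the only call in the other direction (5.15 ± 1.12, adjusted p = 0.0116), with the reservation on its signal in Ha-ras tumors given above and a value of 2.72 without Ha-ras tumor 2.

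These 8 of 158 antibodies (1 higher, 7 lower) were 11 under quantile normalization, with 4 higher and 7 lower, 3 in the authors' value table and 3 after scaling to the Alexa647 rows. Under both of the last, RPS6KA3_P-T353/T356 (adjusted p up to 0.216), RPS6KA1_P-T573 (up to 0.157), STAT3_P-S727 (up to 0.244), STAT3 and PDK1_P-S241 lost their calls. MAPK3_P-T202/Y204 and MAP2K1_P-S217/S221 passed in every alternative run. STAT3 was lost in 7 of the 16 runs that left out 1 sample (Ctnnb1 tumor 4, PB control livers 5 and 6, no-PB control livers 2 and 3, Ha-ras tumors 1 and 3, adjusted p up to 0.0968) and PDK1_P-S241 in 11 of 16 (up to 0.123), all but Ctnnb1 tumors 1, 5 and 6, no-PB control liver 2 and Ha-ras tumor 1. In the MAPK/ERK list 4 of 18 were lower (adjusted p = 0.0404, but adjusted p = 0.262 with an estimated correlation). In the xenobiotic list 1 of 17 was higher, 3 adjusted over the list alone (adjusted p = 3.2e-04, but adjusted p = 0.262 with an estimated correlation), and in the phosphorylation-site list 6 of 50 were lower (adjusted p = 0.00767, but adjusted p = 0.638 with an estimated correlation). Of the pairs, MAPK3_P-T202/Y204 relative to MAPK3 (-1.76 ± 0.31, adjusted p = 0.00154) and STAT3_P-Y705 relative to STAT3 (0.91 ± 0.24, adjusted p = 0.0361) passed. The second was lost in 11 of the 16 runs that left out 1 sample (adjusted p up to 0.141), all but those without Ctnnb1 tumors 2, 6 or 7, PB control liver 4 or no-PB control liver 1. With 1 sample left out, GLUL passed without Ha-ras tumor 1 (7.22), CYP2E1_2 without Ctnnb1 tumor 6 (2.39) and CYP2C8 without Ctnnb1 tumor 1 (1.21). With all samples, GLUL (5.11 ± 1.92, adjusted p = 0.152), CYP2E1_2 (2.14 ± 0.67, adjusted p = 0.089), CYP2C8 (1.10 ± 0.33, adjusted p = 0.074), CTNNB1 (-0.87 ± 0.56), CTNNB1_P-S675 (-0.53 ± 0.28), CTNNB1_P-T41/S45 (-0.35 ± 0.24), HRAS (-0.08 ± 0.17), MAPK3 (-0.27 ± 0.24), MAP2K1 (0.03 ± 0.30), MAP2K2 (-0.19 ± 0.18), AKT1 (-0.11 ± 0.19) and AKT1_P-S473 (-0.18 ± 0.24) did not pass.

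**Figure D3:**
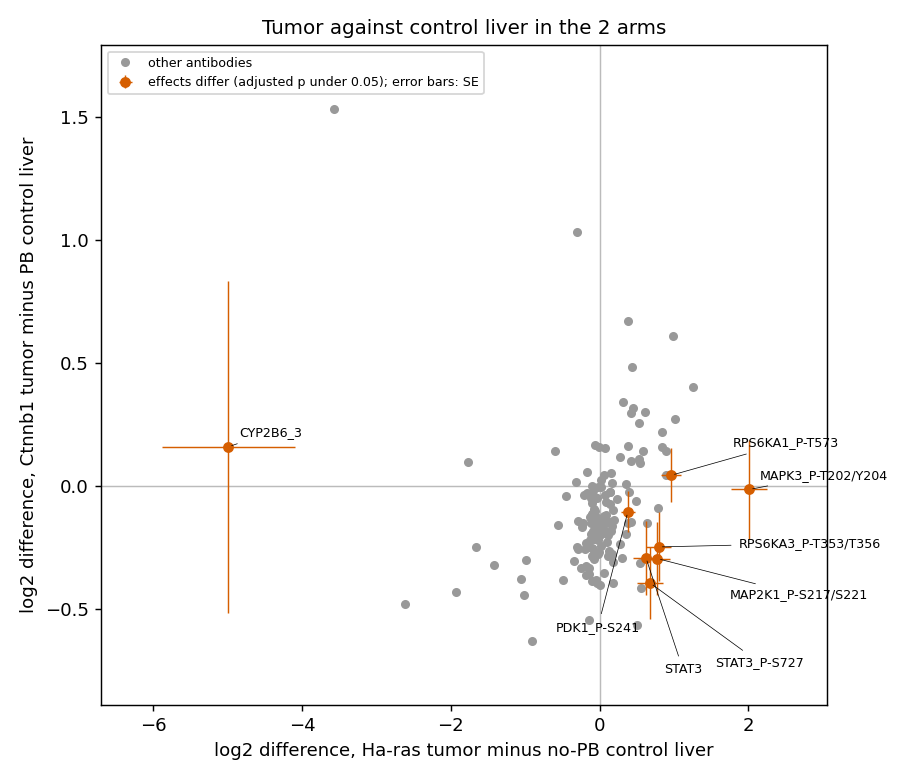
Log2 difference of tumor and control liver per antibody in the Ha-ras arm (horizontal axis) and the Ctnnb1 arm (vertical axis), with the 8 antibodies whose effects differed in orange and error bars of 1 SE. MAPK3_P-T202/Y204 lies at 2.01 and -0.01 and CYP2B6_3 at -4.99 and 0.16.

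Other fixed groups showed few changes. None of the 15 cell cycle antibodies and none of the 12 antibodies to tyrosine kinases passed in any of the 5 comparisons (limma, camera adjusted p at or above 0.261 and 0.146 for the lists). Of the 3 chaperone and cell stress antibodies, 1 passed in each of 2 comparisons, EIF2A, which the PI3K list also holds. The 4 antibodies to reference proteins and the 2 to proteins of other cell types (CDH2 and ITGAV) had no call. GAPDH, the only antibody of the carbohydrate list, read from 0.0975 to 1.85 over the samples without a call.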

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

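All tests of explanations in this part, other than the counts over other splits of the samples, were chosen after the results had been seen. Of the 47 antibodies tested for a sample far from the rest of the 7 Ctnnb1 tumors, 2 (4.26%) passed the outlier limit. This is no more than the 1 in 20 or so that chance gives. CYP1A2_1 was low in tumor 6, with a gap to the next tumor of 0.761 of the whole range (centred log2 of 0.94 against 4.19). GLUL was low in tumor 7, with a gap of 0.743 of the range of the 6 tumors with a positive signal (3.94 against 5.85).

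Tumor 6 was also the tumor without a positive GLUL signal. CYP1A2, CYP2E1 and GLUL are products of beta-catenin activity in liver. Of the 3 other antibodies to CYP1A2 and CYP2E1, tumor 6 was the lowest of the 7 Ctnnb1 tumors for 2, both against CYP2E1, and not for CYP1A2_2, so failed readings of single antibodies stay open. A Ha-ras tumor of the arm without PB under a wrong label would lie within the range of the Ha-ras tumors. For 4 of 4 antibodies tumor 6 lay outside that range (MAPK3_P-T202/Y204, CYP2B6_3, CYP2C8 and POR). CYP2C8, for example, had a centred log2 of 3.29 in tumor 6 against 0.0533 or less in the Ha-ras tumors. All 4 were calls between the tumor types in a comparison that included tumor 6, and their choice favours this outcome. The values argue against such a label error for these 4 antibodies only. CYP2C8 and POR were also higher in control liver with PB than without, and CYP2B6_3 had a large difference there that did not pass. A Ha-ras mutation in a tumor with PB is thus addressed by MAPK3_P-T202/Y204 alone (centred log2 1.5 against 2.85 or more). Control liver mixed into the sample would leave values between control liver and the other tumors. Tumor 6 lay below every PB control liver for CYP1A2_1 (0.94 against 3.76 or more) and GLUL, the 2 antibodies by which it was picked. Its GLUL signal was not positive (-0.0233), and the authors' value table gives it a log2 ratio of -0.49 to the median control liver. The values speak against a mixture only as far as these 2 readings hold. A sample from outside these groups also stays open, and no biological explanation was tested, since the labels give no group that sets tumor 6 apart.

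The tumor effects of the 2 arms differed in 8 antibodies by the test of the difference itself, with log2 differences of -2.02 for MAPK3_P-T202/Y204, -1.06 for MAP2K1_P-S217/S221, -1.04 for RPS6KA3_P-T353/T356, -0.915 for RPS6KA1_P-T573, -1.07 for STAT3_P-S727, -0.911 for STAT3, -0.483 for PDK1_P-S241 and 5.15 for CYP2B6_3. Of 100 splits within the arms, 2 gave as many antibodies, the real one included. The share is under 0.05, although the highest other split gave 9 antibodies against the real 8. Each split mixed tumors with control livers inside both arms, which removes both tumor effects. The count therefore bears on a tumor effect in either arm and cannot decide whether the 2 effects differ.

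The 6 MAPK/ERK antibodies lower in Ctnnb1 than in Ha-ras tumors had a median log2 difference of -1.01. Scaling of the samples is argued against as the whole account, since with scaling to the Alexa647 rows the median was -0.835 and 5 of 6 passed. The amount of the proteins is argued against for the set by the phospho to total differences, with a median of -0.735 over 5 pairs, 3 of which passed, although the MAP2K1 pair was lost in 7 of 10 runs that left out 1 sample. A PB effect of the kind seen in control liver is argued against by a median of -0.0755 between the control livers for the same antibodies. A PB effect present in tumors alone stays open beside the tumor genotype, because the design gives no Ha-ras tumor with PB and no Ctnnb1 tumor without. A difference between the arms in carcinogen dose or age at injection stays open too.

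The absence of calls in Ctnnb1 tumors against PB control liver did not rest on 1 outlying sample, since leaving out any 1 of the 10 samples gave at most 0 antibodies. For larger spread among the Ctnnb1 tumors, the SD among them was 1.24 times that pooled over the other groups in the median over antibodies, which lies between the bounds set for and against. The median SD was 0.213 in the Ctnnb1 and 0.205 in the Ha-ras tumors, which had 22 calls. It was lower in the control livers, 0.108 with PB and 0.144 without, so these values point both ways. The median SE (0.145 against 0.172) cannot bear on this. The single fit shares the spread per antibody over all groups, so the SE follows the group sizes. This explanation was not decided. All 100 of 100 splits of these samples gave at least the real number of 0, as any split must, so this count decides nothing, and the highest other gave 12.

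For the direct comparison of the tumor types, 1 of 100 splits gave as many antibodies, the real one with 30, and the highest other gave 4. A share of 1 in 100 is the smallest that these splits can give, and it cannot separate the genotype from PB or from other differences between the arms. With 3 samples against 3 there are 10 splits, too few for a share under 0.05. The real number was 22 and the highest other 1 for Ha-ras tumors against control liver, and 3 and 0 for the control livers, with 1 split as large in each.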

How the results depend on the processing

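Array weights (in 4 of the comparisons), the Alexa647 scaling, blank subtraction and the filter at 2 times the blank were chosen after the data had been seen. Of 3064 recomputed differences of named antibodies, 2748 kept direction and side of the threshold, 200 lost a call, 54 gained one, 62 moved without a call and 0 turned direction while called. Of the named antibodies with a call, 10 of 22 in Ha-ras tumors, 7 of 28 between the tumors, 2 of 3 in the control livers and 2 of 8 for the difference kept it under every alternative run. With the replicate block left out these were 10, 17, 2 and 2. Where counts changed by over 1.5 times, the cause was not tested except as stated.

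Ctnnb1 tumors against PB control liver gave 1 antibody with array weights. The control livers gave 5 with no centring, 5 with array weights and 8 with the compared groups alone. The difference of the tumor effects gave 3 in the authors' value table, 3 with the Alexa647 scaling, 2 with blank subtraction and that scaling, and 17 with array weights. Phospho to total pairs in Ctnnb1 tumors against control liver fell from 1 to 0 in the authors' value table, where 3 lists passed instead of 0. With an estimated correlation, the lists past the threshold went from 2 to 0 in Ha-ras tumors, from 3 to 1 between the tumors and from 3 to 0 for the difference, which follows from allowing for correlated antibodies.

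With 1 sample left out, the antibodies past the threshold were 0 to 0 in Ctnnb1 tumors, 16 to 20 in Ha-ras tumors, 24 to 35 between the tumors, 2 to 3 in the control livers and 6 to 11 for the difference. Pairs were 0 to 1, 2 to 5, 3 to 11, 0 to 1 and 1 to 2, and lists 0 to 0, 2 to 4, 3 to 4, 1 to 1 and 2 to 3.

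The samples share only a number. Same-numbered tumor and control samples had correlated deviations of 0.095, 0.128 and 0.225 in the PB arm and 0.611, 0.0928 and 0.00615 in the other, the tumors of both arms -0.177, -0.158 and -0.229, and not every sample correlated best with its own number. With the replicate number as a block, antibodies were 0 in Ctnnb1 tumors, 25 in Ha-ras tumors, 8 between the tumors and 7 for the difference. Pairs were 0, 11, 1 and 3, and lists 1, 2, 2 and 2. The block leaves fewer samples with a partner. The control livers share no number, so no block was fitted there. The value table gives no value for the control livers or the direct comparison of the tumors. Signals under 2 times the blank limit what dim antibodies can show.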

Other observations

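The tests on blanks and on shared variation were chosen after the data had been seen. In Ha-ras tumors total STAT3 rose 1.54-fold and STAT3_P-S727, with the reservation on its signal given above, 1.60-fold. Relative to the total, STAT3_P-S727 had a log2 difference of 0.06 ± 0.20 (limma adjusted p = 0.842). STAT3_P-Y705 was 1.66-fold lower relative to the total (adjusted p = 0.016), with a log2 difference of -0.11 ± 0.10 for the site itself. JUN and its kinase site MAPK8_P-T183/Y185 (1.85-fold) were both higher, and the upstream MAP2K4_P-S257/T261 had a log2 difference of 0.43 ± 0.17 (adjusted p = 0.134) and passed with the Alexa647 scaling (0.62, adjusted p = 0.00916).

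The antibodies to reference proteins were not steady. GAPDH read 0.153, 1.16 and 1.85 in the 3 control livers without PB, 0.107, 0.372 and 0.215 in those with PB and 0.124, 0.948 and 0.0975 in the Ha-ras tumors. ACTB ranged from -0.0459 in a PB control liver to 4.03 in a Ha-ras tumor.

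No difference between tumors and control livers passed for the blanks with anti-mouse, anti-rabbit or anti-goat secondary antibody or for the Alexa647 rows by exact permutation tests (8 two-sided tests, smallest adjusted p = 0.8). An exact permutation test of 3 against 3 samples cannot go below p = 0.1.

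A hypothesis formed after the values had been seen was that products of beta-catenin activity vary together among the Ctnnb1 tumors. In 3 relations tested by exact permutation, Pearson's r was 0.694 for CYP1A2_1 and CYP2E1_2 (n = 7, p = 0.098, adjusted p = 0.206; Spearman's rho 0.429, p = 0.354) and 0.755 for GLUL and CYP2E1_2 (n = 6, p = 0.138, adjusted p = 0.206; rho 0.257, p = 0.658). For GLUL and CYP1A2_1 it was, by the same exact permutation, 0.00663 (n = 6, p = 0.989, adjusted p = 0.989; rho 0.0286, p = 1). Without the 2 tumors farthest from the median, r was 0.00334, -0.408 and 0.572, so the first 2 relations rest on those tumors. None of the 3 relations is decided, since the tumors were few and tumor 6, without a logarithm for GLUL, is missing from both relations with GLUL.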
